A study of Rattus norvegicus with 57 samples.

How the data were processed

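Liver RNA from 57 rat samples, 3 per group in 19 groups, was measured on Affymetrix rat arrays. Per the submitters' processing notes the authors used Affymetrix GCOS 2.0, and the deposited probe set intensity values are linear signals whose 2% trimmed mean was 500.2 on each array, so that a global scaling had been applied. The background and summary steps inside that software are not given in the sources used here. A deposited workbook holds the same signals together with the authors' pairwise log2 ratio of each array against each 0 h array, per the file headers. No detection calls were used here.

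Of 31099 probe sets, 57 are array controls. Names were taken from the workbook and updated through the accessions, symbols and synonyms of a RefSeq gene table (assembly GRCr8): 15090 probe sets matched by accession, 2886 by current symbol and 940 by synonym, 943 kept the file's name, and 11170 without a single gene were left out of the main tests. A synonym can lead to a relative of the gene meant. For the 4212 genes with several probe sets the set with the highest mean over all arrays was used. Values were taken as log2(signal + 16), so a fold change is on that scale and understates the change of dim genes. A gene was tested when its highest group mean exceeded 7.379, the median of all log2 values, which left 10331 of 13860 genes.

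A limma model with a mean per group was fitted to all 57 arrays (38 residual degrees of freedom, 9.41 prior degrees of freedom, trended prior). PH was compared with sham at each time, both arms with 0 h, and the early phase with the late phase through contrasts, any change over the 9 times through a moderated F test, and PH with sham over the 9 times through group means with time as a block. Adjusted p-values are Benjamini-Hochberg values from limma, over the genes of each comparison, and genes under 0.05 were called. The 39 gene lists, fixed before the data were examined together with the tests, the alternatives and the naming rule, were tested with camera from limma with an estimated correlation between genes, adjusted over 351 pairs of list and time. A list needed at least 5 measured members. Of the 351 pairs 119 passed, 61 higher and 58 lower after PH.

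Genes were named by a rule: per time the 5 largest rises and falls among called genes whose PH arrays all lay on one side of all sham arrays, 5 each way for early against late, 5 each way with the same sign at all times for the test over 9 times, the 10 largest changes of each arm against 0 h, up to 4 members per list and time with the largest change past the threshold, and a panel of 57 genes, of which 54 passed the filter. Uncharacterised symbols were not named, and a few genes that meet the rule are not given in the text. The Eif2s3 probe set falls outside the rule and was chosen after its values were seen.

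The steps were tested on simulated data with 67, 67 and 66 changed genes of each size per comparison. For PH against sham at 24 h, 40.3%, 82.1% and 89.4% of genes changed by 0.5, 1 and 2 on the log2 scale were recovered among 10331 genes, and 0.10% of the unchanged genes were called. For the test over 9 times the recovered shares were 13.4%, 74.6% and 100%. For the lists, 4 of 4 shifted lists were called and 0 of 346 unchanged pairs. The simulated noise was independent between genes, so this does not test lists whose genes vary together. Far fewer genes were changed than the real comparisons called, and the recovered shares depend on that fraction.

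Alternatives were no filter on dim genes, a pseudocount of 1 or 64, quantile normalization, median centring, the mean of a gene's probe sets, the replicate number as a block, fits of the compared groups alone, a preset correlation and fry for the lists, and leaving out each array or time in turn. R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.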

Results

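Gene expression was measured in the liver of Sprague-Dawley rats aged 12 weeks, per the labels, after partial hepatectomy (PH), the surgical removal of part of the liver, after which the remnant grows back. Control animals had a sham operation (sham), the same surgery without removal of liver. Tissue came from the right lobe, with the blood flushed out through the portal vein, at 9 times between 2 and 168 h after either operation, and from a 0 h control group. Each of the 19 groups had 3 arrays, 57 in all, hybridised to an Affymetrix rat expression array. The labels call 2 h after PH the priming phase, 6 to 36 h the proliferation phase and 72 to 168 h the termination phase, and give no sex of the animals. They also call the 3 arrays of a group technical replicates, while the design text says that the experiment was repeated 3 times, so p-values measure only the spread between these arrays, which may be technical. Every array was scaled to a 2% trimmed mean of 500.2, and the median signal per array lay between 128.8 and 197.8. The number of arrays limits the precision. Of 13860 genes, 10331 passed the filter on dim genes, and their median residual standard deviation was 0.183 on the log2 scale. Values after ± are standard errors of the fitted difference, unless called SD. At a single time that difference is between groups of 3 arrays. For early against late it is a contrast over the groups of both phases. For the test over 9 times it comes from group means with time as a block, and its error from the spread between times.

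The first comparison set PH against sham at the same hour after operation. It asks how removal of liver changes expression beyond the effect of surgery and of the time since it. Time of day is held equal only if both arms were collected at the same clock hour, which was not tested. The number of genes called at a Benjamini-Hochberg adjusted p under 0.05 was 4016 at 2 h, 5913 at 6 h, 6278 at 12 h, 5435 at 24 h, 5682 at 30 h, 6675 at 36 h, 5829 at 72 h, 3058 at 120 h and 3768 at 168 h. Of these, 813, 1804, 2078, 1494, 1730, 2399, 1760, 380 and 462 changed at least 2-fold, in the same order of times. The median difference over all genes tested lay above 0.1 on the log2 scale at 12 h (0.16) and 30 h (0.12), so that small rises at these hours are read against that shift.

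**Figure D1:**
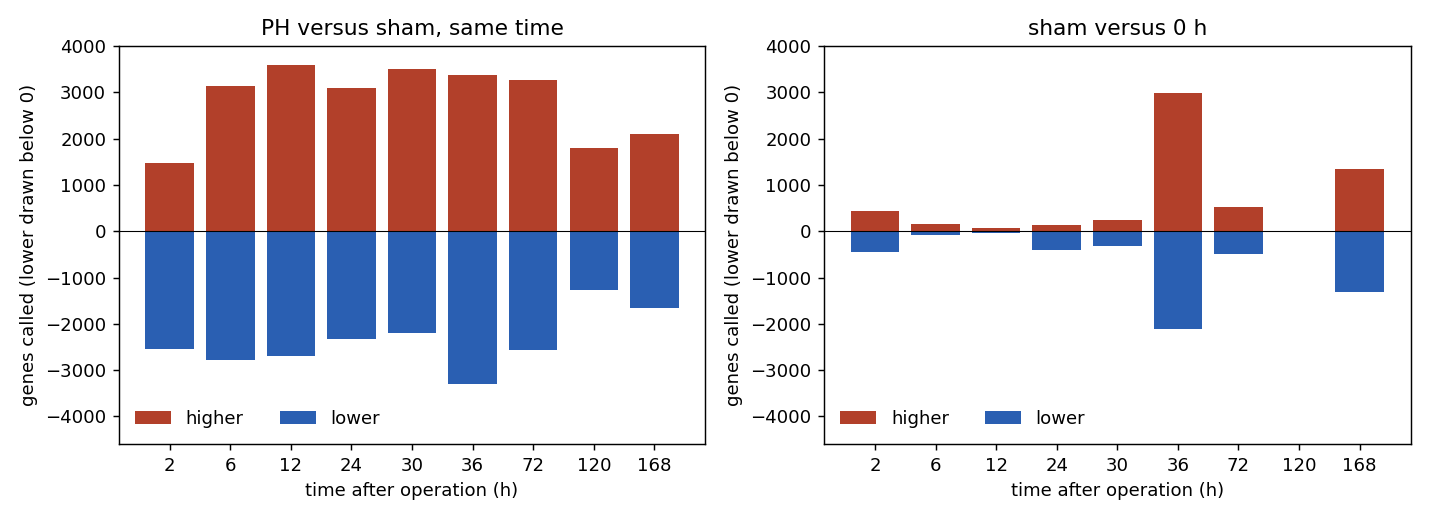
Number of genes called at each time after operation, higher above 0 and lower below 0, for PH against sham at the same hour (left) and sham against 0 h (right). PH against sham ranged from 3058 genes at 120 h to 6675 at 36 h, and sham against 0 h reached 5109 at 36 h.

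Several genes that differ in expression between male and female rat liver separated PH from sham, and this accompanies every gene group described for PH against sham, except at 24 h. Cyp2c11, a male-specific cytochrome P450, had a mean of 15.03 ± 0.13 (SD, n = 3) on the log2 scale after PH at 2 h, against 8.71 ± 1.44 in sham and 7.66 ± 0.20 at 0 h. It was higher than sham by 6.33, 5.50, 5.48, 3.52, 1.84, 3.64, 4.76 and 4.83 at 2, 6, 12, 30, 36, 72, 120 and 168 h. At 24 h the difference for Cyp2c11 was -0.58 and did not pass the test, but passed it with median centring (-0.73), quantile normalization (-0.68), a fit of these groups alone (-0.58) and without PH replicate 3 (-0.77). A probe set for Eif2s3, a translation initiation factor gene with copies on both sex chromosomes in rodents, stood between 4.81 and 6.76 in all 30 sham and 0 h arrays, at or above 7.89 in PH arrays at all times except 24 h, and at or below 5.54 in the PH arrays at 24 h. That probe set was picked after its values were seen, out of 16 probe sets looked up for 6 gene names, and was the only 1 of the 16 to follow the male-biased genes. As a list, the 16 male-biased genes passed the camera test at 2, 120 and 168 h, and not at 6, 12, 30, 36 and 72 h (adjusted p = 0.577, 0.676, 0.965, 0.15 and 0.286), with 7, 6 and 7 members lower at 6, 12 and 30 h. The other Eif2s3 probe sets lay between -0.83 and -0.37 from sham at 2 h, between 0.29 and 1.66 at 24 h and between -0.02 and 1.48 at 72 h. Arm and these genes coincide within each time, so the counts at the other 8 times could not be run without them.

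**Figure D2:**
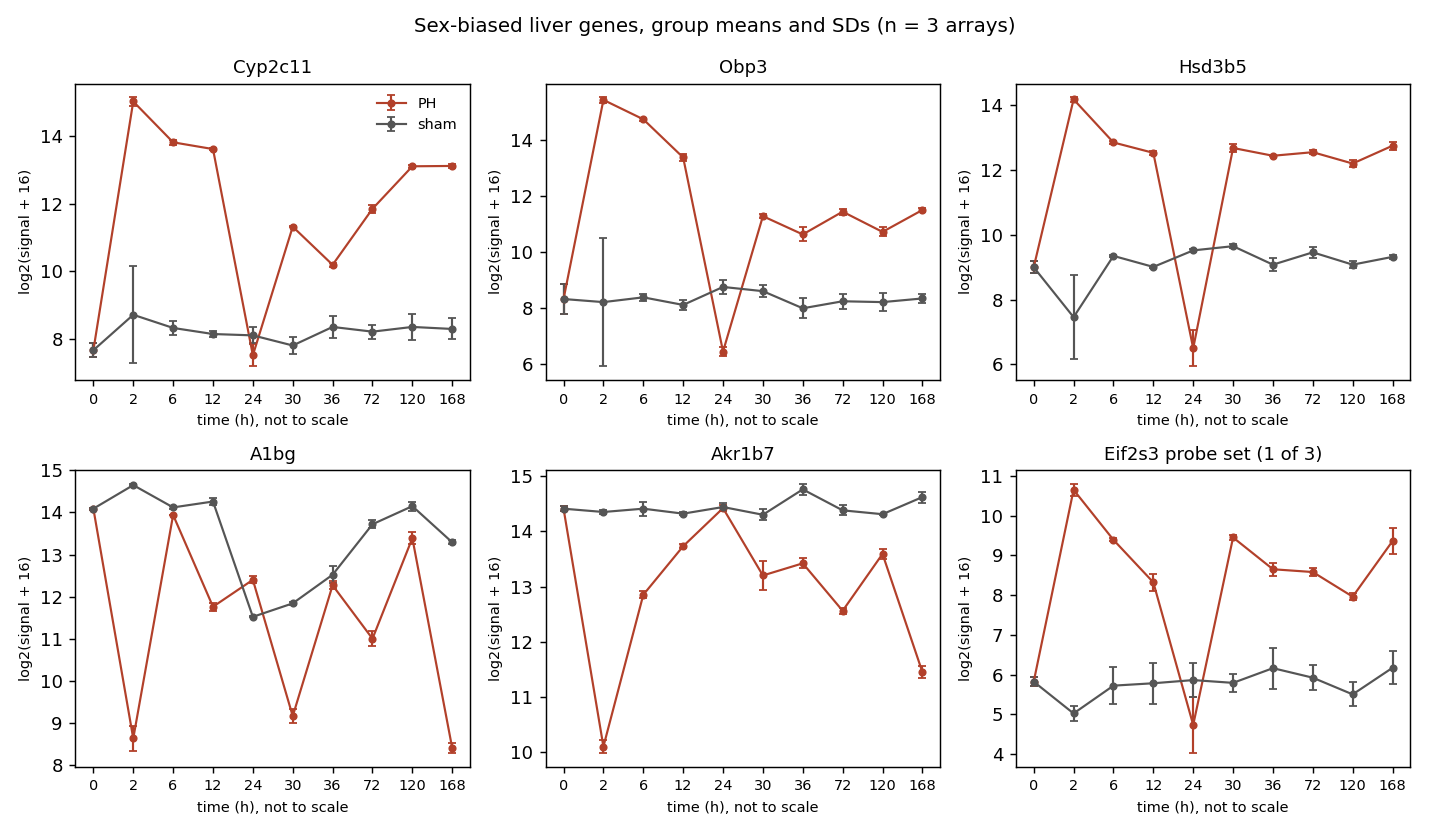
Mean and SD (n = 3 arrays) on the log2(signal + 16) scale of 5 sex-biased liver genes and the Eif2s3 probe set, by time after PH (red) or sham operation (grey). The male-biased genes Cyp2c11, Obp3 and Hsd3b5 lay above sham after PH at every time except 24 h, when the PH mean of Cyp2c11 was 7.51.

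At 2 h, genes of the early cytokine and growth response were higher after PH than after sham, together with the sex-biased genes. Of 15 measured targets of JAK/STAT signalling, 13 rose and 0 fell (median 1.18, camera adjusted p = 7.33e-06), led by Socs2 (3.52), Cish (2.90), Socs3 (2.27 ± 0.29) and Bcl3 (2.05). Among 24 immediate early genes 16 rose and 3 fell (median 0.83, adjusted p = 3.15e-05), with Gadd45b at 3.25, Btg2 at 2.81, Myc at 2.46 ± 0.23 and Cebpd at 2.17. Fos, the classic immediate early gene, differed by -0.14 and did not pass the test, with means of 10.74 after PH, 10.88 after sham and 9.94 at 0 h. Against 0 h, 14 of the 24 were also higher in sham at 2 h and 0 lower. The acute-phase list rose in 13 of 22 members (median 0.33, adjusted p = 0.0496), including the chemokine gene Cxcl1 (3.19), the siderophore-binding Lcn2 (2.95) and the interleukin-1 antagonist Il1rn (2.52). Neutrophil markers rose in 5 of 7 members (adjusted p = 0.000746), among them Il1r2 (2.74) and S100a8 (2.24). Interferon-response genes rose in 12 of 27 and fell in 3 (adjusted p = 0.000295), with Ifit1 at 1.86 and Mx2 at 1.78. In sham at 2 h, 9 of these 27 were lower than 0 h and 0 higher (median -0.16), so part of the difference lies in the sham arm. For Mx2 the mean of its probe sets gave -0.01.

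Cell-cycle genes lay below sham at 2 h. Of 55 mitosis genes 38 fell and 2 rose (median -0.94, adjusted p = 0.000343), including Cdc20 (-1.91) and Mki67 (-1.69), and 27 of 40 DNA replication genes fell (median -0.67, adjusted p = 0.000498), including Rrm2 (-1.85). Against 0 h the arms moved in opposite directions: after PH 20 mitosis genes fell and 2 rose (median -0.42), and after sham 11 rose and 0 fell (median 0.50). For DNA replication genes, 10 fell and 3 rose after PH, and 8 rose and 0 fell after sham. The Mki67 means were 7.29 after PH, 8.98 after sham and 7.94 at 0 h. Heat-shock genes fell in 8 of 13 members (adjusted p = 0.000919), with Dnajb1 at -1.15, and proteasome subunits in 19 of 27 (adjusted p = 0.041). The 5 largest rises were those of Obp3 (7.20 ± 0.42), Sult1e1 (6.97 ± 0.25), Hsd3b5 (6.73 ± 0.25), Cyp3a2 (6.60 ± 0.28) and Cyp2c11 (6.33 ± 0.29), and the largest falls included those of A1bg (-6.02 ± 0.10), the pancreatic carboxypeptidase gene Cpa1 (-5.47 ± 0.27), Akr1b7 (-4.26 ± 0.08) and Sult2a2 (-4.10 ± 0.08). Of the male-biased liver list 12 of 16 members rose and 2 fell (median 4.45, adjusted p = 0.000581), and of the female-biased list 11 of 13 fell and 1 rose (median -1.95, adjusted p = 1.67e-05). Adjusted over the list alone, 13 JAK/STAT, 16 immediate early and 16 acute-phase genes rose, and 39 mitosis and 28 DNA replication genes fell. In total 1480 genes rose and 2536 fell. Socs2 of the JAK/STAT list and Sult1e1 also belong to the male-biased list. In the authors' own ratios Cpa1 was -3.1. Without sham replicate 1 Obp3 stood at 8.50, Sult1e1 at 7.76, Hsd3b5 at 7.46, Cyp3a2 at 7.42 and Cyp2c11 at 7.13, and without sham replicate 3 Obp3 was 6.34 and Cyp2c11 5.72.

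At 6 h, genes for making ribosomes rose, while genes for making fat and bile acids fell. Of 39 ribosome biogenesis genes 37 rose and 0 fell (median 1.2, adjusted p = 2.19e-07), with the nucleolar proteins Gar1 (2.23), Heatr1 (2.06), Ddx21 (2.02) and Nop56 (1.93) in the lead. Fatty acid synthesis genes fell in 18 of 19 members (median -1.32, adjusted p = 4.95e-06), among them the elongase Elovl6 (-3.79 ± 0.08), the acyltransferase Gpam (-3.59 ± 0.17) and the lipogenic transcription factor Srebf1 (-3.50). Bile acid synthesis and transport genes fell in 15 of 19 (median -1.23, adjusted p = 7.33e-06). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, fell most of all genes at -5.10 ± 0.07, and the bile acid receptor Nr1h4 (-1.90) and its target Nr0b2 (-3.56) fell too. Immediate early genes were higher in 19 of 24 members and lower in 2 (median 1.02, adjusted p = 5.89e-05), including Gadd45b (3.06), Myc (2.57) and Fos (1.41), and JAK/STAT targets were higher in 12 of 15 (adjusted p = 0.00364).

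T and NK cell markers also rose at 6 h, in 16 of 19 members with 1 lower (median 1.45, adjusted p = 0.00876), led by Gzmm (3.17), Cd69 (3.07) and Cd3d (2.08). Neutrophil markers rose in 6 of 7 (adjusted p = 0.00795), with Il1r2 at 3.98. Genes of oxidative phosphorylation fell in 25 of 31 members and rose in 1 (median -0.50, adjusted p = 0.00795), and those of the pericentral zone, the hepatocytes near the central vein, in 12 of 16 with 1 higher (adjusted p = 0.0092), including Avpr1a (-3.17) and Aldh1a1 (-2.19). The largest rises were in Obp3 (6.34 ± 0.42), Cyp2c11 (5.50 ± 0.29), the cross-linking enzyme Tgm1 (5.31 ± 0.50), the myeloid receptor Lilrb4 (4.64 ± 0.46) and the ficolin Fcnb (4.57 ± 0.57), and the further largest falls in C5h1orf210 (-4.48 ± 0.16) and Glyat (-3.81 ± 0.15). Leaving out single sham arrays gave 4.65 to 5.81 for Tgm1 and 3.99 to 5.33 for Fcnb. With p adjusted over the list alone, 37 ribosome biogenesis and 19 immediate early genes rose, and 18 fatty acid synthesis and 15 bile acid genes fell. The Eif2s3 probe set stood 3.67 above sham. Of the genes called, 3129 rose and 2784 fell. After centring each array on its median the share of rises went from 52.9% to 41.5%.

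At 12 h genes of several metabolic pathways lay below sham. Fatty acid synthesis genes fell in 18 of 19 members (median -2.14, adjusted p = 9.71e-07), led by Pnpla3 (-4.45), Acss2 (-2.70) and Elovl6 (-2.65), and bile acid genes in 17 of 19 with 1 higher (median -0.86, adjusted p = 1.67e-05), including the uptake carriers Slco1a4 (-4.74 ± 0.08) and Slc10a1 (-2.79) and again Cyp7a1 (-4.55 ± 0.07). Genes of the urea cycle and amino acid metabolism fell in 28 of 35 members and rose in 2 (median -1.06, adjusted p = 0.00305), with Cth at -4.38, Bhmt at -3.78 and Sds at -3.50 (-2.84 without PH replicate 2). Oxidative phosphorylation genes fell in 29 of 31 (median -0.78, adjusted p = 0.000931), including Sdhd (-1.43) and Ndufa9 (-1.36). Drug-metabolising genes fell in 26 of 34 and rose in 5 (adjusted p = 0.0233), the rises including Cyp2c11 (5.48) and Cyp3a2 (3.94). Pericentral markers fell in 13 of 16 with 1 higher (adjusted p = 0.00349) and periportal markers in 14 of 19 with 2 higher (adjusted p = 0.00849), with Aldh1a1 at -4.67 ± 0.07 and Otc at -2.76.

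Ribosome biogenesis genes were higher in 36 of 39 members at 12 h (median 0.91, adjusted p = 3.51e-05). Extracellular matrix genes rose in 18 of 27 (median 0.82, adjusted p = 0.00754), with the protease inhibitor Timp1 at 3.98 and Spp1 at 1.64. Spp1 lost its call without PH replicate 2 or 3 (1.5 and 1.52), without sham replicate 1 (1.18) and with quantile normalization (1.19). Markers of other cell types rose with them: neutrophils in 7 of 7 (adjusted p = 0.0037), T and NK cells in 15 of 19 (adjusted p = 0.0163) and B or plasma cells in 8 of 11 (adjusted p = 0.000777). The last list was led by the class II genes RT1-Bb (2.46), RT1-Da (2.18) and Cd74 (1.99), which other antigen-presenting cells also express. The largest single rises were in Tgm1 (5.59 ± 0.50), Cyp2c11 (5.48 ± 0.29), Obp3 (5.26 ± 0.42), Zfp37 (5.06 ± 0.49) and Lcn2 (4.46 ± 0.24), and the largest falls included Cpa1 (-4.81 ± 0.27) and the peroxisomal enzyme Ehhadh (-4.78 ± 0.11), with Cpa1 at -2.7 in the authors' own ratios. The Eif2s3 probe set stood 2.54 above sham at this time. The PH arrays at 12 h also had higher median signals (187.7 to 197.8, against 128.8 to 144.4 in sham) and lower 3'/5' signal ratios, from 3.54 to 4.52 for beta-actin against 4.85 to 5.36 in sham, and from 1.72 to 1.84 for Gapdh against 2.29 to 2.66. Adjusted over the list alone, 18 fatty acid synthesis, 28 urea cycle and 29 oxidative phosphorylation genes fell. Of the genes called, 3591 rose and 2687 fell, and the share of rises went from 57.2% to 42.8% with median centring and to 45.5% with quantile normalization.

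At 24 h the genes of DNA synthesis and cell division rose together. All 40 DNA replication genes were higher (median 2.46, adjusted p = 2.46e-11), including the ribonucleotide reductase subunit Rrm2 (4.93 ± 0.09), the licensing factor Cdt1 (4.35), Gmnn (4.09), the helicase subunit Mcm6 (3.95) and the sliding clamp Pcna (2.62). Of 55 mitosis genes 54 rose and 0 fell (median 3.64, adjusted p = 2.46e-11), led by the kinases Ttk (5.35 ± 0.48) and Pbk (5.22 ± 0.43), the kinesin Kif20a (4.96 ± 0.57) and the cyclin Ccna2 (4.89). Genes of the G1/S transition rose in 15 of 17 members (median 1.26, adjusted p = 7.95e-05), with Ccne2 at 4.34, E2f8 at 3.81 and Ccnd1 at 2.33, and the mitotic transcription factor Foxm1 rose by 3.48. Adjusted over the list alone, 40 DNA replication, 55 mitosis and 15 G1/S genes rose.

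Immediate early genes were higher than sham at 24 h in 21 of 24 members with 0 lower (median 1.11, adjusted p = 1.52e-07 and 21 adjusted over the list alone). Fos stood 4.63 above sham, and Nr4a2 (3.29), Gadd45b (3.25), Btg2 (3.20) and Jun (2.49) were also higher. At 12 h, 12 of these 24 genes had been higher and 3 lower, and the list did not pass the test (median 0.58, adjusted p = 0.0516). Genes of the unfolded protein response rose in 15 of 22 and fell in 3 (adjusted p = 0.0129), with Sdf2l1 at 1.73, and heat-shock genes rose in 8 of 13 (adjusted p = 0.0307). Fatty acid synthesis genes fell in 16 of 19 and rose in 2 (median -1.63, adjusted p = 2.4e-06), including Pnpla3 (-2.89) and Acly (-2.49), and urea cycle and amino acid genes fell in 26 of 35 and rose in 4 (adjusted p = 0.00332). The largest falls were in the glutathione transferase Gstp3 (-5.58 ± 0.18), Ehhadh (-4.18 ± 0.11), RT1-N3 (-3.69 ± 0.25), the pro-apoptotic Bmf (-3.64 ± 0.35) and the serine dehydratase Sds (-3.37 ± 0.22), and the microtubule protein Spag5 was among the largest rises (5.02 ± 0.30). In all 3102 genes rose and 2333 fell, and the share of rises went from 57.1% to 43.4% after median centring. The beta-actin 3'/5' signal ratios of the PH arrays at 24 h, a measure of RNA integrity and of how complete the labelled copies are, were 2.47 to 2.86, against 5.09 to 5.71 in sham at 24 h. Sham replicates 2 and 3 at 24 h lay closer together than any other pair of replicates (SD of the difference over bright genes 0.082, next lowest pair 0.122, correlation 0.986), so this group may hold fewer than 3 separate samples. With sham 24 h arrays 2 and 3 averaged, the count of PH versus sham 24 h was 4936.

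At 30 h the cell-cycle genes stayed far above sham, and genes for making fatty acids and cholesterol lay below it. Mitosis genes were higher in 54 of 55 members (median 3.40, adjusted p = 3.78e-10) and DNA replication genes in 40 of 40 (median 2.08, adjusted p = 6.55e-10), with Kif20a at 5.00 ± 0.57, the proliferation marker Mki67 at 4.92 ± 0.17, Rrm2 at 4.91 ± 0.09 and Troap at 4.88 ± 0.32. Cyclin D1 (Ccnd1) stood 3.06 above sham, and G1/S genes rose in 15 of 17 and fell in 1 (adjusted p = 0.000557). Fatty acid synthesis genes fell in 17 of 19 (median -1.95, adjusted p = 8.42e-08), led by Thrsp (-4.11 ± 0.07), the desaturase Scd (-4.02) and Fads2 (-3.56), and cholesterol synthesis genes fell in 18 of 25 and rose in 4 (adjusted p = 0.00866), with Insig1 at -1.76. The fatty acid oxidation list did not pass the test at 30 h, with 13 of 24 members higher and 10 lower (adjusted p = 0.929). Bile acid genes fell in 14 of 19 and rose in 2 (median -0.94, adjusted p = 3.51e-05), urea cycle and amino acid genes in 29 of 35 with 2 higher (adjusted p = 0.000729), and drug-metabolising genes in 28 of 34 with 4 higher (adjusted p = 0.00422).

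Of the clock list at 30 h, 4 of 15 members rose and 8 fell (adjusted p = 0.0365). Per3 (3.45) and Nr1d1 (2.74) were higher and Npas2 (-2.10) and Per1 (-2.06) lower. Against 0 h, 4 clock genes were higher and 9 lower after PH at 30 h, and 0 higher and 2 lower after sham. A different hour of collection in the 2 arms was not tested. Ribosome biogenesis genes rose in 35 of 39 and fell in 1 (adjusted p = 5.38e-05), and neutrophil markers in 6 of 7 (adjusted p = 0.00652). The thioesterase Acot1 rose by 4.90 ± 0.55, and the largest falls beside Thrsp were in Ehhadh (-4.91 ± 0.11), Gstp3 (-4.76 ± 0.18), RT1-N3 (-4.72 ± 0.25) and the methyltransferase Bhmt (-4.59 ± 0.09). The female-biased list fell in 12 of 13 members (median -1.23, adjusted p = 8.8e-05), and the Eif2s3 probe set stood 3.66 above sham. Adjusted over the list alone, 54 mitosis and 40 DNA replication genes rose, and 18 fatty acid synthesis genes fell. Of the genes called, 3493 rose and 2189 fell, a share of rises of 61.5%, and 39.6% after median centring. Replicate 3 of PH at 30 h had a beta-actin 3'/5' ratio of 9.77, the highest of all arrays.

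At 36 h mitosis genes were higher in 55 of 55 members (median 2.81, adjusted p = 3.88e-09) and DNA replication genes in 37 of 40 (median 1.47, adjusted p = 1.97e-07). Kif20a (4.34 ± 0.57), Troap (4.33 ± 0.32), Gtse1 (4.28 ± 0.49), the polo-like kinase Plk1 (4.21 ± 0.46) and Ect2 (4.17 ± 0.18) showed the largest rises. Cholesterol synthesis genes, lower at 30 h, were higher in 21 of 25 with 2 lower (median 0.68, adjusted p = 0.00884), including Sqle (2.52) and Msmo1 (2.08). Against the sham groups at 30 and 72 h the cholesterol list was not called, with 8 members higher and 10 lower (median -0.02, adjusted p = 0.693). Genes of fatty acid synthesis fell in 15 of 19 and rose in 3 (median -1.40, adjusted p = 0.00013), with Pnpla3 at -3.61 ± 0.28. The other largest falls were in the clock gene Npas2 (-3.92 ± 0.20), IgG-2a (-3.89 ± 0.08), the mitochondrial carbonic anhydrase Car5a (-3.72 ± 0.11) and Sult2b1 (-3.57 ± 0.33). With p adjusted over the list alone, 55 mitosis and 38 DNA replication genes rose.

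Markers of non-hepatocyte cells lay below sham at 36 h, at the hour when the sham group itself stood apart from 0 h, with 5109 genes called between them. Macrophage markers fell in 15 of 16 members (median -2.08, adjusted p = 2.56e-05), including the Kupffer cell lectin Clec4f (-2.87) and C1qa (-2.57), endothelial markers in 15 of 16 (median -1.34, adjusted p = 0.000103), and B or plasma cell markers in 11 of 11 (median -1.84, adjusted p = 7.8e-05). T and NK cell markers fell in 15 of 19 (adjusted p = 0.00522). Against the mean of the sham groups at 30 and 72 h, an alternative chosen after seeing the data, the macrophage median was -1.15 with 13 of 16 lower and 1 higher, 6 of 19 T and NK cell markers were lower and that list was not called (adjusted p = 0.217), 6 of 11 B or plasma cell markers were lower (median -0.41), the endothelial median was -0.74, the mitosis median 3.38, and 5576 genes were called in place of 6675, of which 1199 changed at least 2-fold in place of 2399. Of the 5576, 4030 were called in the same direction against both controls and 360 in opposite directions. Cyp2c11 was 1.84 above sham and the Eif2s3 probe set 2.49, and 3367 genes rose and 3308 fell. The median signal of the sham arrays at 36 h was 172.5 to 189.5, against 130.5 to 137.7 after PH.

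At 72 h interferon-response and matrix genes were higher than sham, and cell-cycle genes remained above it. The largest rises were in the chemokine genes Ccl20 (6.76 ± 0.54), Ccl2 (5.56 ± 0.47) and Cxcl2 (4.99 ± 0.27), Fcnb (5.38 ± 0.57, or 6.06 without sham replicate 1) and Cyp3a2 (4.62 ± 0.28). Interferon-response genes rose in 22 of 27 members and fell in 2 (median 0.79, adjusted p = 6.69e-06), led by Cxcl10 (4.21), Gbp2 (3.40) and Rsad2 (2.30). Extracellular matrix genes rose in 20 of 27 with 0 lower (median 1.10, adjusted p = 0.000321), including Timp1 (2.73), Col6a2 (2.62) and Col1a2 (2.40). Mitosis genes were higher in 49 of 55 (median 1.82, adjusted p = 9.46e-07) and DNA replication genes in 33 of 40 (median 1.05, adjusted p = 1.14e-05). Neutrophil markers rose in 7 of 7 (median 2.42, adjusted p = 0.0013) and macrophage markers in 13 of 16 with 1 lower (median 0.76, adjusted p = 0.00641), with Itgam at 4.06 and Lyz2 at 2.39.

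Among the genes lower at 72 h were the carboxylesterase Ces1d (-3.44 ± 0.07), Sult2b1 (-3.41 ± 0.33), Tkfc (-3.17 ± 0.12) and the growth factor gene Egf (-3.13 ± 0.08). Genes of fatty acid synthesis fell in 13 of 19 and rose in 5 (median -1.15, adjusted p = 0.000674), with Elovl6 at -2.71 and Elovl5 at 2.76, and urea cycle and amino acid genes fell in 25 of 35 and rose in 4 (adjusted p = 0.00818). The female-biased list fell in 12 of 13 (median -1.36, adjusted p = 0.00015), with the transcription factor Cux2 at -2.89, and the Eif2s3 probe set stood 2.65 above sham. Adjusted over the list alone, 50 mitosis, 34 DNA replication and 21 matrix genes rose. The PH arrays at 72 h had beta-actin 3'/5' ratios of 2.17 to 2.66, against 4.80 to 5.05 in sham. Of the genes called, 3257 rose and 2572 fell, and the share of rises went from 55.9% to 45.6% after median centring.

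At 120 h fewer genes differed, 1793 higher and 1265 lower. Mitosis genes were still higher in 35 of 55 members (median 1.02, adjusted p = 9.46e-07, 40 adjusted over the list alone), among them Kif20a (2.31, or 1.44 and no call without sham replicate 1) and Ccnb1 (2.15), while 4 of 40 DNA replication genes rose and 1 fell, and that list did not pass the test (median 0.05). Extracellular matrix genes rose in 13 of 27 (median 0.70, adjusted p = 0.000283), with the collagens Col3a1 (1.91) and Col5a2 (1.83). Cholesterol synthesis genes rose in 19 of 25 and fell in 1 (adjusted p = 0.00403), and fatty acid oxidation genes rose in 16 of 24 (adjusted p = 0.00298), with Eci1 at 1.08 (0.43 and no call with the mean of its probe sets). Single genes with large rises were Serpinb9b (5.30 ± 0.56), Cyp3a2 (4.77 ± 0.28), Cyp2c11 (4.76 ± 0.29), the signalling gene Wnt4 (3.55 ± 0.53) and the activin antagonist Fst (3.42 ± 0.46). The protease inhibitor A2m fell by 3.44 ± 0.06, and Nptx2 (-2.49 ± 0.17), Dmbt1 (-2.14 ± 0.27), Zfp142 (-2.03 ± 0.30) and Inmt (-2.0 ± 0.31) were also lower, with Zfp142 at -1.2 in the authors' own ratios and -1.19 without PH replicate 3. The male-biased list rose in 11 of 16 and fell in 1 (median 1.39, adjusted p = 0.0157). The beta-actin 3'/5' ratios at 120 h were 3.53 to 3.90 after PH and 5.25 to 5.88 after sham, and those of Gapdh 1.92 to 1.98 and 2.15 to 2.43.

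At 168 h the cell-cycle genes lay below sham. Of 55 mitosis genes 27 fell and 1 rose (median -0.63, adjusted p = 0.000413, 29 lower adjusted over the list alone), including Ttk (-1.55) and Plk1 (-1.45), and of 40 DNA replication genes 13 fell and 1 rose (median -0.42, adjusted p = 0.0013), including Rrm2 (-1.64). Ttk lost its call without PH replicate 3 (-1.27), with the mean of its probe sets (-1.02) and in a fit of these groups alone, and Plk1 in that fit and without PH replicate 1 (-1.28) or sham replicate 1 (-0.90). Genes of oxidative phosphorylation rose in 24 of 31 (median 0.32, adjusted p = 0.00522) and of fatty acid oxidation in 19 of 24 with 3 lower (adjusted p = 0.00152), while fatty acid synthesis genes fell in 12 of 19 and rose in 1 (median -0.67, adjusted p = 6.7e-05). Immediate early genes rose in 13 of 24 and fell in 1 (median 0.61, adjusted p = 0.000139), with Btg2 at 2.56 and Fos at 1.83. Erythroid genes rose in 5 of 6 (median 1.68, adjusted p = 0.00686), including Ahsp (2.35), Alas2 (1.99) and Hbb (1.91), in tissue from which the blood had been flushed. The largest rises were in Cyp3a2 (4.90 ± 0.28), Cyp2c11 (4.83 ± 0.29), Fst (4.48 ± 0.46), Ust5r (3.61 ± 0.17) and Hsd3b5 (3.43 ± 0.25). The largest falls included A1bg (-4.89 ± 0.10), Cux2 (-3.35 ± 0.12), Akr1b7 (-3.17 ± 0.08) and Aldh1a7 (-2.92 ± 0.15). Of these 9 genes, Cyp3a2, Cyp2c11, Ust5r, Hsd3b5, A1bg, Cux2 and Akr1b7 belong to the sex-biased lists, and 2108 genes rose and 1660 fell in all. The sham group at 168 h itself differed from 0 h in 2645 genes. Against 0 h, mitosis genes fell in 16 members and rose in 1 after PH (median -0.41), and rose in 8 and fell in 0 after sham (median 0.20), so part of the difference lies in the sham arm. Sham replicate 1 at 168 h had a beta-actin 3'/5' ratio of 7.53, against 3.86 and 4.59 in the others.

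**Figure D3:**
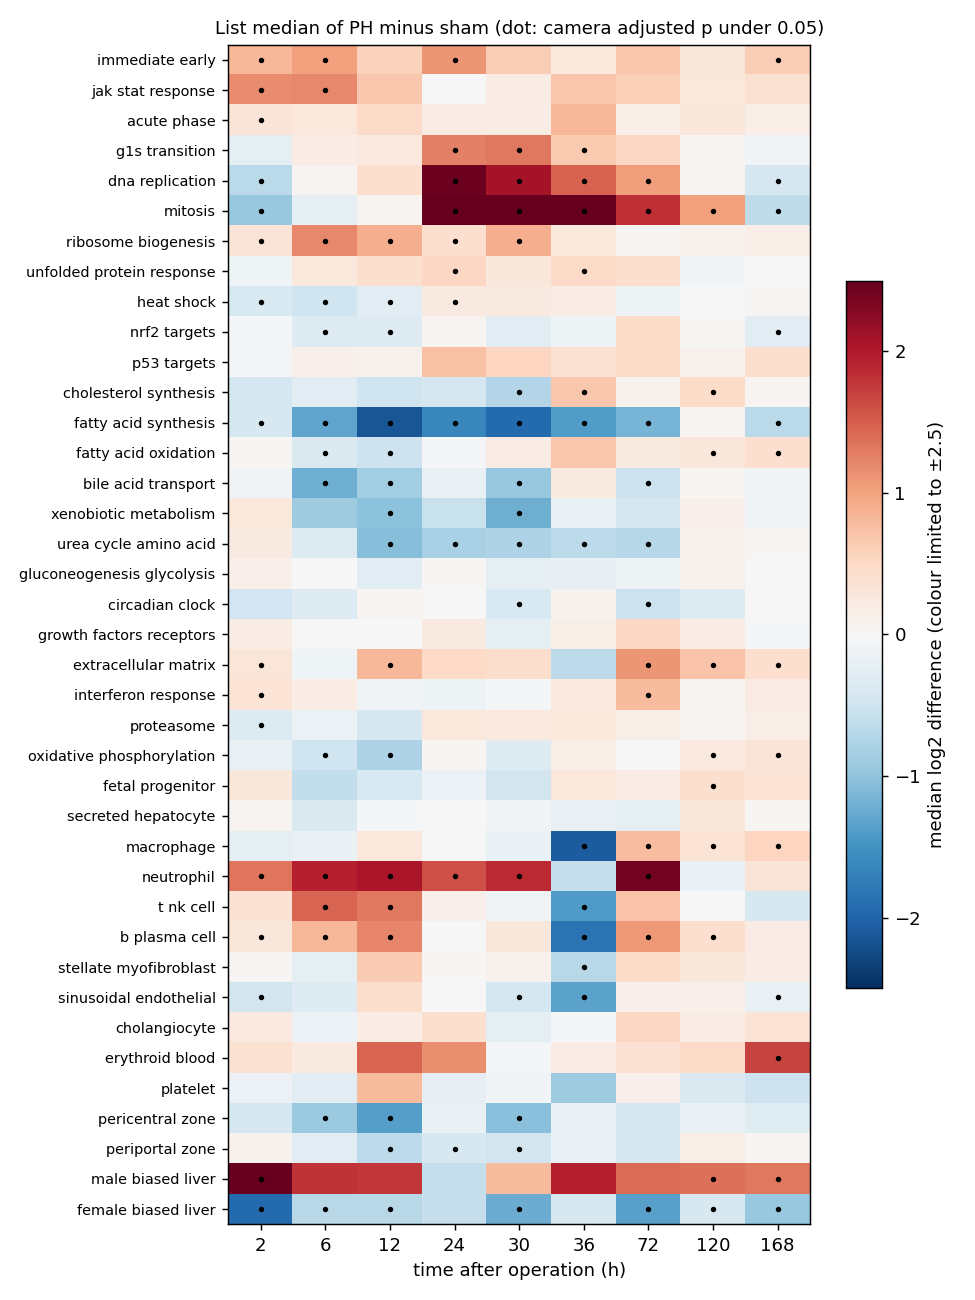
Median PH minus sham difference (log2, colour) of the 39 gene lists at each time, with a dot where the camera adjusted p was under 0.05. The mitosis list went from a median of -0.94 at 2 h to 3.64 at 24 h and -0.63 at 168 h.

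**Figure D4:**
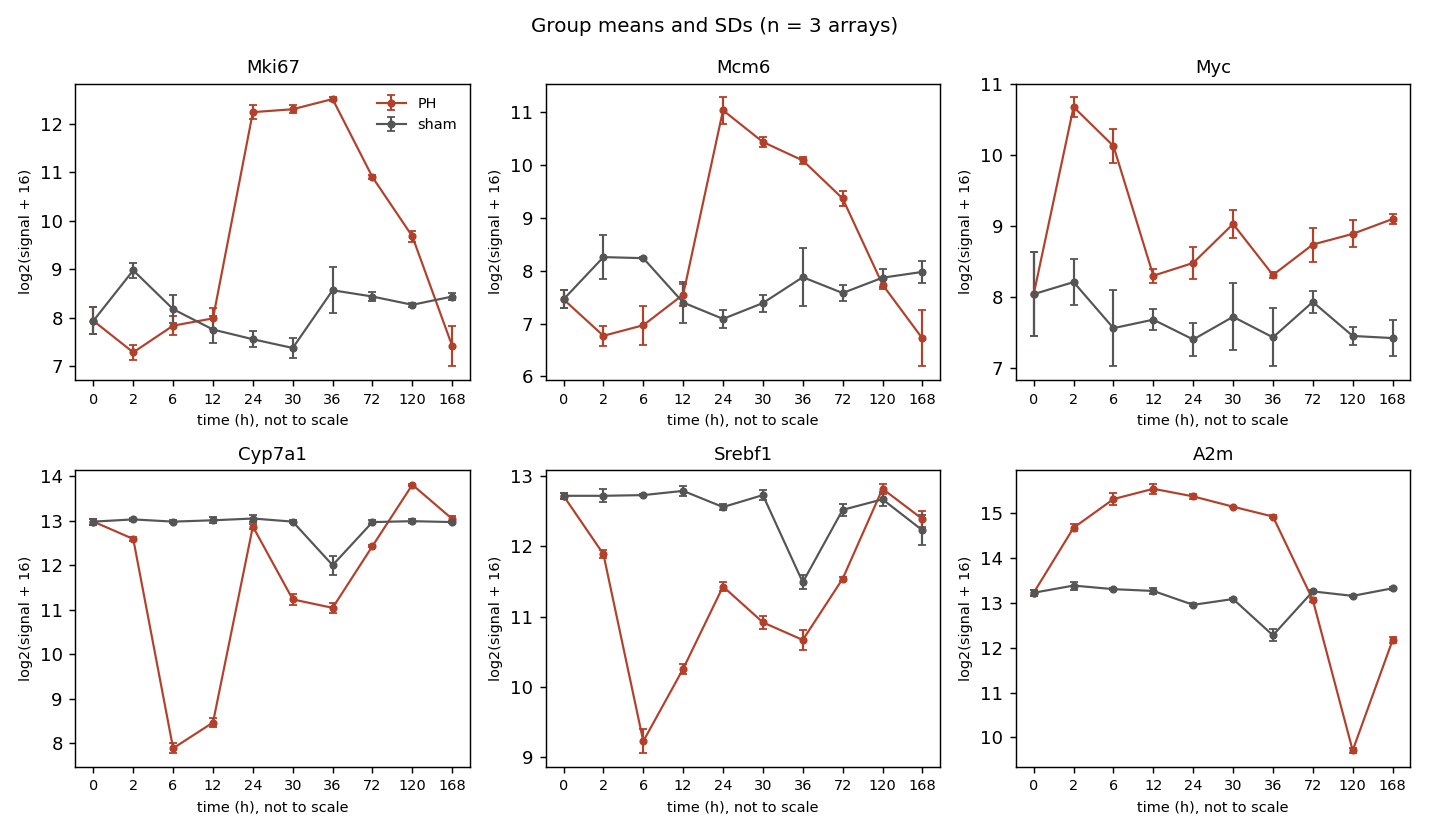
Mean and SD (n = 3 arrays) on the log2(signal + 16) scale of 6 genes of the panel by time after PH (red) or sham operation (grey). Mki67 and Mcm6 were above sham from 24 to 72 h, Myc was highest after PH at 2 h (10.68), and Cyp7a1 after PH was lowest at 6 h.

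The next comparison asked which PH effects differed between the proliferation phase (6 to 36 h) and the termination phase (72 to 168 h), by a test of the difference itself. It called 5816 genes, of which 3068 were higher relative to sham in the early phase and 2748 in the late phase. The test compares mean effects, and its error came from the spread between arrays of a group. A gene that differed at a single time can therefore be called, and the spread between times of a phase is not measured. Mitosis genes were higher early in 51 of 55 members and DNA replication genes in 37 of 40 with 1 lower, and ribosome biogenesis genes in 34 of 39. The largest early excess was in A2m (3.88 ± 0.04), an acute-phase protein of the rat, which stood 2.65 above sham at 36 h and -3.44 from it at 120 h. It was followed by Troap (2.72 ± 0.24), Cgref1 (2.66 ± 0.30), Reg3b (2.61 ± 0.30) and Nup107 (2.51 ± 0.37). Fst (-4.00 ± 0.34), Ehhadh (-3.65 ± 0.08), Gstp3 (-3.33 ± 0.13), Tsx (-3.28 ± 0.19) and Sds (-3.11 ± 0.16) were higher late. Fatty acid synthesis genes were lower early in 17 of 19 members with 1 higher, drug-metabolising genes in 28 of 34 with 3 higher, and oxidative phosphorylation genes in 27 of 31. The male-biased list was lower early in 12 of 16. The early times include 24 h, when the median of that list lay below sham (-0.60), so the phases are not balanced for these genes.

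A test that counted each group once and took its error from the spread between the 9 times called 2127 genes, 1211 higher and 916 lower after PH. Of these, 827 had the same sign at all 9 times, 440 higher and 387 lower. Among these 827, Lcn2 rose most (3.42 ± 0.24), followed by Ust5r (3.20 ± 0.33), Tgm1 (2.67 ± 0.49), Napsa (2.55 ± 0.36) and Marveld1 (2.51 ± 0.29), while Cyp2c11 (3.92 ± 0.58) and Cyp3a2 (3.89 ± 0.59), not higher at all 9 times, rose further. Their largest falls were in Sult2b1 (-2.39 ± 0.39), Trim24 (-2.23 ± 0.26), Glyat (-2.06 ± 0.37), Ppp1r3b (-2.04 ± 0.29) and Car5a (-1.99 ± 0.39). Of 39 ribosome biogenesis genes 25 were called higher and 0 lower, and of 19 fatty acid synthesis genes 12 lower and 0 higher. With the group mean of the Eif2s3 probe set as a covariate, an alternative chosen after seeing the data, 170 genes were called, and of the 10 genes named here only Lcn2 (3.71 ± 0.48) and Ust5r (1.42 ± 0.27) kept their call. The others were Tgm1 at 1.80 ± 0.94, Napsa at 2.36 ± 0.72, Marveld1 at 1.28 ± 0.41, Sult2b1 at -3.24 ± 0.73, Trim24 at -1.46 ± 0.45, Glyat at -2.59 ± 0.71, Ppp1r3b at -1.48 ± 0.56 and Car5a at -2.86 ± 0.73, each with a larger standard error than without the covariate. The Eif2s3 term itself was called for 10 genes. For PH against sham, 2313 genes had an unadjusted limma p under 0.05 with the covariate and 3729 without it. The covariate nearly coincides with the arm at every time except 24 h, so the lower count does not show that it accounts for the lost calls. Without 24 and 72 h, also chosen after seeing the data, 511 were called.

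Against the 0 h group, 9490 genes changed at some time after PH by a moderated F test over the 9 times, and 7042 after sham. The largest changes after PH were in Cyp2c11 (7.37), Obp3 (7.09), Cyp3a2 (5.66) and Hsd3b5 (5.18) at 2 h, Gstp3 (-5.94) and Ttk (5.37) at 24 h, Ccl20 (5.92) at 72 h, A1bg (-5.69) at 168 h, Cyp7a1 (-5.10) at 6 h and Zfp37 (5.06) at 12 h. Cyp2c11, Obp3, Cyp3a2, Hsd3b5 and A1bg are sex-biased genes.

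In the sham arm, 885, 243, 114, 532, 551, 5109, 1031, 7 and 2645 genes were called against 0 h at the 9 times in order. Macrophage markers were higher in sham at 36 h in 15 of 16 members with 1 lower (median 0.99), B or plasma cell markers in 9 of 11 (median 1.16), T and NK cell markers in 14 of 19 (median 0.92), endothelial markers in 11 of 16 (median 0.48), stellate cell markers in 8 of 18 (median 0.47), and neutrophil and platelet markers in 3 of 7 and 3 of 6, with 0 lower in these lists. Bile acid genes were lower in 14 of 19 (median -0.81), fatty acid synthesis genes in 11 of 19 with 1 higher, and cholesterol synthesis genes lower in 19 of 25 with 1 higher (median -0.86). The largest changes in sham were in Sirt6 (3.16), Hsd17b13 (-2.54), Hand2 (2.42), Yipf3 (-2.42), Zic2 (2.41) and Stk19 (2.40) at 36 h, the pancreatic carboxypeptidase gene Cpb1 (-2.86) and A1bg (-2.56) at 24 h, and Aldh1a7 (-2.5) and Slc7a8 (2.32) at 2 h. Hsd17b13 was -0.8 in the authors' own ratios, and Stk19 at 36 h was 3.23 without 0 h replicate 1. Slc7a8 lost its call without 0 h replicate 1, with 1.92 and an adjusted p of 0.0993. Other settings and single arrays moved several of these counts by over 1.5 times. A fit of the groups compared alone called 26 genes at 6 h, 8 at 12 h and 3 at 120 h, quantile normalization 134 at 6 h, the mean of probe sets 1 at 120 h, and no filter on dim genes 4 at 120 h. Without sham replicate 2 or 3 the count was 368 or 19 at 6 h, 318 or 300 at 24 h, 286 or 292 at 30 h, 635 or 621 at 72 h and 0 (limma, 602 at an unadjusted p under 0.05) or 4 at 120 h. At 12 h it was 33, 23 or 188 without sham replicate 1, 2 or 3. Without 0 h replicate 1, 2 or 3 it was 101, 89 or 147 at 6 h, without replicate 2 or 3 it was 41 or 47 at 12 h, without replicate 2 it was 667 at 72 h and 4 at 120 h, and without replicate 3 it was 307 at 30 h.

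Among single genes followed at every time, called or not, the growth factor receptor gene Met was higher after PH than after sham at 24 h (2.02), 36 h (0.90), 72 h (2.66), 120 h (1.09) and 168 h (1.43), and its ligand gene Hgf at 12 h (2.28) and 72 h (1.94). At 72 h the Met means were 8.25 after PH, 5.59 ± 0.91 (SD) after sham and 7.01 at 0 h, so a low sham level accounts for part of the difference. At 168 h they were 6.63 after PH and 5.19 ± 0.76 (SD) after sham, both below 0 h. The difference at 168 h thus reflects the low sham level and no rise of Met above 0 h. The Hgf sham means at 12 and 72 h were 5.57 ± 0.85 and 5.56 ± 0.97 (SD), a dim signal. Hgf at 72 h lost its call without sham replicate 1 (1.38), and Met at 168 h in a fit of these groups alone (2.3 in the authors' own ratios). Met also lost its call at 36 h without PH replicate 2 (0.78) or sham replicate 2 (0.84) and with a pseudocount of 1 (1.01), and at 120 h without PH replicate 1 or 3 (0.99 and 0.95) or sham replicate 1 or 2 (0.96 and 0.91). Afp, a fetal liver gene, lay below sham at 6, 12 and 30 h (-1.81, -1.77 and -0.70). The gluconeogenic gene G6pc1 was lower at 2, 6, 12, 24, 30 and 72 h (-1.66, -1.23, -0.65, -0.35, -1.40 and -0.74) and higher at 120 h (0.30). The mean of its probe sets gave -0.02 and no call at 24 h. At 36 and 168 h that mean gave 0.859 and 0.645, both called, against 0.062 and 0.15 with no call for the probe set in use. The G6pc1 result at these times thus depends on the probe set. Calls of Alb, Tgfb1 and Pck1 at several times depended on single arrays or on the normalization, and no direction is given for them at those times. Tgfb1 was higher at 30 h (2.48, or 2.07 to 2.89 with an array left out) and 72 h (2.90, or 2.78 to 3.03). Its sham means there were 5.41 and 5.53, a dim signal. Il6, Areg and Hbegf were below the filter on dim genes.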

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

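All tests of the 3 patterns weighed below were chosen after the results were seen, while the splits of the arrays and the test of early against late were planned.

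The median of the male-biased liver genes lay above sham after PH at 2, 6, 12, 30, 36, 72, 120 and 168 h and below it at 24 h (-0.60), and that of the female-biased genes lay below sham at all 9 times (-0.58 at 24 h). An exchange of the PH and sham groups at 30, 36, 72 or 120 h is argued against, since at each of these times at least 37 more of 55 mitosis genes were called higher than 0 h in the PH arrays than in the sham arrays, and an exchange at 6 or 12 h likewise, with at least 35 more of 39 ribosome biogenesis genes. At 2 or 168 h an exchange stays open. The PH mean of Cyp2c11 at 2 h lies 4.73 on the log2 scale above the highest of all sham and 0 h arrays. That value cannot decide it, since exchanged whole groups would lie as far apart. Against 0 h at 2 h, JAK/STAT targets were higher in 14 of 15 members after PH and 3 after sham. Ribosome biogenesis genes were higher in 16 and 1 of 39, which also runs with the labels, and mitosis genes in 2 and 11 of 55. No list was weighed in a test of an exchange at 2 or 168 h. Animals of different sex in the arms may account for the pattern. At 8 of 8 times with Cyp2c11 over 1 above sham the Eif2s3 probe set was over 2 above sham. Yet that set was picked because it follows these genes, and 10 of 31042 probe sets on the array do. Only 1 of 16 sets looked up follows. That count decides nothing, because a set for a copy on the X chromosome need not be higher in males. A response of the liver within 2 h stays open too. The A1bg difference from sham at 2 h, read as a fall within 2 h, would need a transcript half-life of at most 19.9 minutes with no synthesis. Against 0 h the largest A1bg change after PH was -5.69, at 168 h, so a bound set from 0 h is longer. Such a response cannot be told apart from a difference in sex, or at 2 or 168 h from an exchange. The labels give no sex, and arm and signal coincide within each time.

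The sham group at 36 h stood apart from 0 h and from the neighbouring sham times. A smaller share of hepatocytes in that tissue would raise the markers of every other cell type alike, and those of B or plasma cells (median 1.16), neutrophils (1.05), macrophages (0.99), platelets (0.94) and T and NK cells (0.92) rose, while bile acid and fatty acid synthesis genes fell (both -0.81). It is argued against as the whole cause for these arrays, since macrophage markers rose more than stellate cell markers by a difference of medians of 0.52 (permutation p = 0.00141). Among members above 8 on the log2 scale at 0 h, where the pseudocount compresses little, they rose more than 5 stellate (0.71, permutation p = 0.00944) and 14 endothelial markers (0.51, permutation p = 0.00103). The permutations shuffle genes measured on the same arrays and measure no spread between animals. Secreted hepatocyte genes did not fall together, with 7 of 18 higher and 8 lower (median -0.15). Alb stood at 16.70 in sham at 36 h against 15.42 at 0 h. That level depends on the scaling: the Alb difference of PH from sham at 36 h was -1.046, and -0.155 with no call under quantile normalization. A difference in RNA preparation or array handling stays open. The SD over genes was 1.51 times that between sham at 30 and 72 h, but any cause would raise it, so it does not point to handling. The highest signal on the sham arrays at 36 h was 104063.6 to 127695.4, against at most 94222.2 on any other array. A difference in handling cannot be told apart from a change in the animals, because the group was a single time point. No biological explanation was tested.

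Immediate early genes lay above sham at 24 h in 21 of 24 members. Low levels in the sham arrays at 24 h account for part of this, as 9 of the 24 were lower in sham than at 0 h and 0 higher (median -0.345). Fos stood at 8.37 in sham and 9.94 at 0 h, and the list median was 1.11 against sham and 0.77 against 0 h. Low sham levels are argued against as the whole cause, since 16 of the 21 were also higher than 0 h, with Fos 3.06 above it. The exact binomial p of 0.0266 treats genes measured on the same arrays as independent. The low 3'/5' ratios of the PH arrays at 24 h may contribute: at 72 h, when PH arrays had low ratios too, 9 of the 21 reached at least 0.5 of their difference at 24 h (exact binomial p = 0.664), which leaves it open. A difference in the animals or their handling at 24 h was not tested.

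The test of early against late called 5816 genes, a difference between the mean effects of the early and the late times. Its error came from the spread between arrays, so a gene that differed at a single time can be called. The difference from sham at 2 h minus that at 24 h was 6.91 for Cyp2c11, 9.5 for Obp3 and -6.89 for A1bg, a difference between times. Early minus late was 3.88 for A2m, -4.00 for Fst and -3.65 for Ehhadh. In values no comparison used, PH at 30 h replicate 3 had a beta-actin 3'/5' ratio of 9.771, against at most 5.098 at 0 h. Of 5793 probe sets without a single gene that passed the filter, 2567 were called for PH against sham at 24 h. Groups of 3 arrays were not tested for single arrays apart from the rest.

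Other splits of the same arrays were counted for each result. For each single time, 1 of 10 splits gave as many genes, the real one, and 10 splits are too few for a share under 0.05. The real counts for PH against sham were 4016, 5913, 6278, 5435, 5682, 6675, 5829, 3058 and 3768, with 3, 7, 0, 1, 37, 19, 1, 0 and 443 as the highest of the others (limma, adjusted p), and for sham against 0 h they were 885, 243, 114, 532, 551, 5109, 1031, 7 and 2645, with 7, 3, 4, 10, 1, 253, 0, 0 and 293. For results over several times, 1 of 100 splits, the real one, gave as many. This excludes a chance split of these arrays, but not a chance difference between animals if the arrays are technical replicates. The counts were 9490 against at most 3516 for PH at any time, 7042 against 2754 for sham at any time, 9539 against 3336 for PH against sham at any time, 5816 against 2048 for early against late, 119 against 4 for the lists and 2127 against 296 over 9 times. For early against late the splits exchanged PH and sham arrays within each time, and each time kept its phase. That count thus does not test the grouping of the times into phases.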

How the results depend on the processing

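The alternatives with the sham groups at 30 and 72 h, the Eif2s3 covariate, the averaged sham arrays, the authors' ratios, the sets without 24 and 72 h or without 36 h, and 24 h only were chosen after seeing the data, and the others before the data were examined. Of 214 values of the counts for PH against sham, the counts over several times and the lists, 206 stayed within 1.5 times the count in use. The others were 305 list calls with fry, 1283, 1232 and 1321 genes over 9 times without 24, 30 or 72 h (range 1232 to 2257), 511 without 24 and 72 h, 170 with the Eif2s3 covariate, and 5114 and 5435 genes with 24 h only for PH at any time against 0 h and against sham. The covariate takes a degree of freedom from 9 pairs, and the cause of the other moves was not tested. Leaving out arrays gave 3535 to 3607 genes at 2 h, 5505 to 5597 at 6 h, 5766 to 5964 at 12 h, 4912 to 5144 at 24 h, 5204 to 5437 at 30 h, 6146 to 6394 at 36 h, 5353 to 5486 at 72 h, 2620 to 2672 at 120 h and 3255 to 3511 at 168 h. It gave 8775 to 9002 for PH at any time, 5443 to 5896 for sham at any time, 8742 to 9021 for PH against sham at any time, 5005 to 5105 for early against late and 104 to 116 lists. With the replicate number as a block the counts at the 9 times were 4038, 5924, 6298, 5459, 5686, 6667, 5847, 3071 and 3778. The labels do not pair the arrays, and 28 of 57 arrays were closest to an array of their own number, against 19 with numbers shuffled within groups (p = 0.0221), so a weak shared deviation is not excluded, while correlations between PH and sham arrays of a number lay between -0.027 and 0.067. With a pseudocount of 64 the genes changed at least 2-fold were 233 at 120 h and 289 at 168 h. Sign changes were Mx2 at 2 h (-0.006, mean of probe sets), Pck1 at 6 and 30 h (0.185 and 0.144, quantile normalization), and Alb and G6pc1 at 36 h (0.035 and -0.52, against sham at 30 and 72 h), the cause not tested. Under the authors' ratios, 82 of 285 values of followed genes moved by more than the spread between replicates, such as Kif20a at 24 h (6.5), Cyp2c11 at 2 h (7.5) and Itgam at 72 h (5.1), and 203 did not. The values from the deposited workbook were identical and detection calls were not used here, so these alternatives were not run. Signal near background limits dim genes, whose changes the pseudocount of 16 understates.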

Other observations

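The list tests here were chosen before the data were examined, and no test was added. Zonation markers of hepatocytes were lower than sham also at 30 h, in 13 of 16 pericentral members with 1 higher (median -1.05, camera adjusted p = 0.0035) and in 13 of 19 periportal members with 1 higher (median -0.47, adjusted p = 0.00312), and the periportal list at 24 h in 13 of 19 with 2 higher (adjusted p = 0.0154). Endothelial markers fell in 8 of 16 members at 2 h (adjusted p = 0.0166) and 10 of 16 at 30 h (adjusted p = 0.00795). NRF2 targets fell in 10 of 17 members and rose in 3 at 6 h (adjusted p = 0.0255). Ribosome biogenesis genes were higher already at 2 h, in 19 of 39 members with 1 lower (median 0.33, adjusted p = 0.000557). Clock genes fell in 10 of 15 members and rose in 3 at 72 h (adjusted p = 0.0291). Macrophage markers rose in 11 of 16 members at 120 h (adjusted p = 0.00849) and 11 of 16 at 168 h (adjusted p = 0.00522). The lists of p53 targets, glucose metabolism, growth factors, secreted hepatocyte proteins, cholangiocytes and platelets passed the camera test at none of the 9 times.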
